A study of Mus musculus with 96 samples.

How the data were processed

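Liver total RNA from CD-1 mice was profiled on 96 expression arrays, 1 per sample. CD-1 is an outbred stock, so the mice of a group differ in genotype. Per the labels, the mice received PB in the diet, the RNA was extracted with Trizol, and 4 μg per sample was amplified and biotin-labelled with the Enzo system. The labels do not expand PB; in work on the receptor CAR (constitutive androstane receptor, gene Nr1i3) it commonly stands for phenobarbital. The design text gives 5 doses from 0.15 to 150 mg/kg-day and a dose of 0, over 2 or 7 days, whereas the sample titles attach ppm to the same numbers; the unit of the design text is used here, and the conflict was not settled by the data.

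The deposited values are on the log2 scale and had been normalized between arrays by the authors; the method is not given in the sources used here. Over the 96 arrays the lower quartile ran from 3.91 to 4.09, the median from 5.34 to 5.44, the upper quartile from 7.17 to 7.43 and the highest value from 14.86 to 14.97. Arrays give no counts, and the number of arrays per group limits the precision. The table held 45101 probe sets. The 64 control probe sets of the maker were left out. Of the rest, 34945 were annotated with 1 gene symbol, 932 with several and 9160 with none; the last 2 kinds were kept apart and not named. Each gene was represented by the probe set with the highest mean over all arrays, a choice that ignores the groups, which gave 18193 genes; 9010 of them had more than 1 probe set. No genome build is given for the values, and no coordinates were used.

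Samples were grouped by the sex, dose and day in their titles into 24 groups of 4. Whether each array stands for a separate mouse is not stated in the labels, so the spread in every test is that between these samples. A mean per group was fitted to all 96 arrays with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), with 72 residual degrees of freedom and 4.39 prior degrees of freedom. Each dose was set against dose 0 of the same sex and day. In the same fit, the response at 150 was compared between the sexes and between the days, and the dose 0 groups were compared between the sexes. Tests were two-sided, with Benjamini-Hochberg adjustment over the 18193 genes of a comparison and a threshold of 0.05. "Rose" and "fell" are used of genes past that threshold, and SE is limma's standard error of a log2 change.

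Before the data were examined, 34 gene lists were fixed: targets of CAR and enzymes of drug oxidation, conjugation enzymes, transporters, heme synthesis, cell division, growth and apoptosis regulators, the Dlk1-Dio3 cluster, lipid, bile acid and glucose metabolism, stress and inflammatory responses, liver zonation, sex-biased and clock genes, immediate early genes, housekeeping genes, and markers of hepatocytes and other cell types. Of their 688 members, 597 were measured. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 34 lists, and again with the correlation estimated from the residuals. Beside the count of members past the threshold over all genes stands the count adjusted over the list alone. The genes named are those of a rule fixed at the same time: for each comparison of 150 against 0, the 10 largest rises and 10 largest falls among called genes whose 4 treated arrays all lay on one side of the 4 controls; up to 4 members of each list; the 5 smallest adjusted p at each lower dose with a call; the 5 largest differences in each direction for differences between sexes or days; and Cyp2b10, Cyp2c55, Cyp3a11, Cyp1a2, Gadd45b, Mki67, Ccnd1, Myc, Meg3, Nr1i3, Nr1i2, Xist and Ddx3y. Only a part of these is named, and Ddx3y had no probe set of its own here.

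Benchmark doses were computed for Cyp2b10, Cyp2c55, Gadd45b and Mki67 in each sex and day from a Hill curve over the 24 arrays, as the dose at which the curve lies 1 pooled SD above its baseline, with a 95% interval from 1000 parametric resamples. The exponent of the curve was held between 1 and 8, and the dose at its midpoint between 0.01 and 300. No benchmark dose is given where limma did not call the gene at 150. Exact permutation tests were used for scores of 4 arrays against 4, where the smallest two-sided p is 0.0286. Figures were drawn with matplotlib 3.10.9.

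The procedure was tested on simulated data with the same design. Of 50 genes changed 1.5-fold, 44 were recovered, and of 50 changed 2-fold, 48; 14 of 206 calls were false. Over 19 simulated comparisons without a change, 1 gene was called. The simulated genes varied independently, whereas measured genes can be correlated, at an estimated 0.478 within the cell division list. These numbers may therefore not carry over to the real data. Simulated benchmark doses had a median between 0.98 and 1.11 times the true dose, and between 47 and 49 of 50 intervals held it. These simulated curves lay inside the limits of the fit and had the same spread at every dose. Several real fits lay at a limit, and the real spread varied with dose, so this coverage may not carry over.

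Alternatives fixed before the data were examined were quantile normalization across the arrays, leaving out the dimmest 40 percent of genes, all probe sets in place of 1 per gene, a fit on only the arrays of the sexes and days compared, a trend and robust variance in limma, the replicate number as a block, an estimated correlation in camera, an exponential curve, a response level of 2 pooled SD, and leaving out each array in turn. A pseudocount did not apply to log2 values. Added after the data were seen were a fit without a pair of doubted male day 2 arrays, and members of 9 lists counted under several of these settings. No date or batch is given in the files. Replicates with one number correlated little across doses, with mean correlations from -0.001 to 0.044 within a sex and day. The mean for replicate 2 in males on day 7 was 0.103. On day 7 the means were 0.036 in females and 0.044 in males, against -0.012 and -0.015 between different numbers. The numbers were not read as pairs in the main fit. Other endpoints that the design text mentions were not analysed here.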

Results

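Liver RNA of CD-1 mice was measured on 96 arrays. Females and males received PB in the diet for 2 or 7 days at 150, 75, 15, 1.5, 0.15 or 0 mg/kg-day, with 4 arrays in each of the 24 groups. The series title names the purpose as modelling of dose and response for early events in liver tumour formation mediated by CAR. Expression values are on the log2 scale, and arrays give no counts, so their number limits the precision. Over the 96 arrays, medians lay between 5.34 and 5.44. Xist, the transcript that silences an X chromosome in females, averaged 12.35 in untreated females and 5.56 in untreated males.

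Comparisons with dose 0 asked which genes responded to each dose. At 150 mg/kg-day on day 2, 11 of 28 CAR targets and oxidation enzymes and 43 of 49 genes for cell division rose in female livers. Cyp2c55, a cytochrome P450 enzyme, rose from 6.58 ± 0.33 (SD, n = 4) to 13.23 ± 0.26 (SD, n = 4), a log2 change of 6.65 ± 0.43 (SE; adjusted p = 6.02e-21). Cyp2b10, the classic target of CAR in mouse liver, rose from 8.15 ± 0.80 to 13.58 ± 0.03, which was 43.3-fold. Birc5, which encodes survivin, rose by 3.45 ± 0.56 on the log2 scale (SE; adjusted p = 4.66e-06), and Ect2, needed for cytokinesis, rose 11.2-fold. Gadd45b, a stress-inducible gene that limits apoptosis, rose from 7.13 ± 0.19 to 8.91 ± 0.25, or 3.45-fold (adjusted p = 2.92e-07). The steepest falls that met the naming rule were in Dnaic1, which fell by 2.26 on the log2 scale, Hsd3b5, which fell by 2.01, and the long noncoding Hectd2os, which fell by 1.92.

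Of 28 measured CAR targets and oxidation enzymes, 11 rose and 1 fell in females on day 2; adjusted over the list alone, 14 rose and 1 fell. Ephx1, the microsomal epoxide hydrolase, rose 2.76-fold, and Cyp2c38, chosen after its values were seen, was the member that fell, by 2.08-fold (adjusted p = 0.0238); that fall was no longer called without control replicate 1, 2 or 3 or without replicate 1, 2 or 3 at 150. Of 32 conjugation enzymes, 15 rose and 1 fell, against 21 and 2 adjusted over the list alone; the glutathione transferases Gstm3, Gstm2 and Gstt3 rose 6.65-fold, 3.16-fold and 2.91-fold. Of 49 cell division genes, 43 rose and 0 fell, as many as when adjusted over the list alone, and their median log2 change was 1.94; with dim genes left out, 31 members remained, of which 27 rose and 0 fell. Ccnb2, a mitotic cyclin, rose 9.67-fold, Ube2c 8.57-fold and Cdca3 7.58-fold. The proliferation marker Mki67 rose by 2.64 ± 0.49 (SE; adjusted p = 6.59e-05). Of 18 NRF2 targets, which protect against oxidants, 8 rose and 9 did so adjusted over the list alone; Nqo1 rose 2.26-fold and the exporter Abcc4 3.93-fold. With camera, these 4 lists shifted upward against all other genes, with adjusted p = 6.37e-05, 0.000332, 0.00011 and 0.000107 with an estimated correlation. Proteins secreted by hepatocytes shifted downward (adjusted p = 0.0408 with an estimated correlation): 3 of 15 fell, and 4 adjusted over the list alone, with F2, the gene of prothrombin, at 1.14-fold lower.

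PPARα targets and fatty acid oxidation genes shifted downward in females on day 2 at the preset correlation, but adjusted p = 0.263 with an estimated correlation; 7 of 27 fell, and 8 did so adjusted over the list alone. Slc25a20, which carries acylcarnitines into mitochondria, was 1.33-fold lower, a call that ended without replicate 1 at 150; without replicate 2 at 150, 3 members fell. Endothelial markers shifted the same way (adjusted p = 0.35 with an estimated correlation): 4 of 20 fell, and 6 adjusted over the list alone. The count of 4 became 2 without control replicate 1, control replicate 2 or replicate 2 at 150, and 1 without replicate 1 at 150. Outside these lists, the bile salt and conjugate exporter Abcc3 rose by 1.76 on the log2 scale, Alas1, the rate-limiting enzyme of heme synthesis, rose 4.24-fold, and Cyp1a2, an AhR target, 1.76-fold. Rdh9, Ang and Cyp8b1, the last of which makes cholic acid, were 2.68-fold, 2.26-fold and 2.18-fold lower. The neutrophil calprotectin gene S100a8 rose 7.12-fold, while its list had a median of -0.08 and a mean of 0.21. In all, 994 genes passed the threshold, 604 higher and 390 lower; 150 rose and 14 fell by 2-fold or more. Without replicate 2 at 150, 601 genes passed.

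Among males on day 2 at 150 mg/kg-day, 14 of 28 CAR targets and oxidation enzymes and 40 of 49 cell division genes rose. Cyp2b10 rose from 7.46 ± 0.39 to 13.57 ± 0.11 (SD, n = 4 each), a log2 change of 6.11 ± 0.40 (SE; adjusted p = 1.85e-20), and Cyp2c55 rose 65.6-fold. Cyp2c65, a P450 of the subfamily of Cyp2c55, rose from 3.30 ± 0.28 to 8.11 ± 0.82, at least 28.1-fold: a dose 0 mean within or below the lower quartiles of the arrays, 3.91 to 4.09, is not shown to be above background, so changes from such a mean, as folds or on the log2 scale, are read as lower bounds here and below. Rrm2, the regulatory subunit that supplies deoxynucleotides for DNA synthesis, rose from 5.84 ± 0.36 to 8.70 ± 0.21, a change of 2.86 ± 0.32 (SE; adjusted p = 3.23e-10). Gadd45b rose 4.71-fold. Cnmd, which encodes chondromodulin, rose 11.9-fold. Rdh9, Ang and Arrdc2 were 2.92-fold, 2.43-fold and 2.31-fold lower, and the aldehyde oxidase Aox3 and the HDL receptor Scarb1 were 2.09-fold and 2.04-fold lower.

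In these males, 14 CAR targets and oxidation enzymes of 28 rose, against 17 adjusted over the list alone, and 0 fell. Conjugation enzymes had 15 rises and 1 fall, with 19 and 1 adjusted over the list alone; Gstt3, Gstm3 and Gstm4 rose 7.03-fold, 5.77-fold and 2.99-fold. Cell division genes had 40 rises and 1 fall among 49, with 43 and 1 adjusted over the list alone, and a median change of 1.65; with dim genes left out, 25 of 31 rose and 1 fell. Birc5 rose by 3.46 on the log2 scale, Ccnb2 8.73-fold and Mki67 4.98-fold. The member that fell was the replication factor Mcm10, chosen after its values were seen, at 2.06-fold lower (adjusted p = 0.0369), which was not called without control replicate 1, 2 or 4 or without replicate 1, 3 or 4 at 150. Among NRF2 targets, 6 of 18 rose, 10 adjusted over the list alone, and Gsr, glutathione reductase, changed by 0.69 (adjusted p = 9.39e-08). These 4 lists were shifted upward with an estimated correlation, at adjusted p = 1.83e-06, 9.59e-05, 0.000628 and 0.00113. Secreted hepatocyte proteins were shifted downward (adjusted p = 0.0476 with an estimated correlation), with 4 of 15 lower by either adjustment and Apoh at 1.10-fold lower; without replicate 1 at 150, 2 fell.

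A further 7 lists were called in males on day 2 at the preset correlation alone. Fatty acid synthesis shifted upward with 3 of 20 rising and 6 rising and 1 falling adjusted over the list alone (adjusted p = 0.297 with an estimated correlation); Fads1, a desaturase, rose 1.29-fold. PPARα targets shifted downward, with 5 of 27 falling and 6 adjusted over the list alone (adjusted p = 0.282 with an estimated correlation); Ppara itself was 1.62-fold lower, Slc25a20 1.37-fold and the mitochondrial dehydrogenase Acadvl 1.28-fold. Gluconeogenesis and fasting genes shifted downward, with 3 of 12 falling and 4 adjusted over the list alone (adjusted p = 0.175 with an estimated correlation); Fbp1 was 1.20-fold lower. Male-biased genes, 1 of 21 falling by either adjustment, gave adjusted p = 0.496 with an estimated correlation, and female-biased genes, 3 of 22 rising and 4 rising and 1 falling adjusted over the list alone, gave adjusted p = 0.343 with an estimated correlation; Prom1 rose 5.03-fold. Kupffer cell markers had 0 calls of 17 by either adjustment (limma; median -0.32; adjusted p = 0.687 with an estimated correlation). Endothelial markers had 2 falls of 20, and 6 adjusted over the list alone (adjusted p = 0.343 with an estimated correlation), with 1 fall without control replicate 1 or without replicate 1 or 2 at 150. Pericentral genes, not called by camera (adjusted p = 0.0918, and 0.566 with an estimated correlation), had 2 of 16 rising and 3 falling, 2 and 5 adjusted over the list alone; Cyp1a2, a member, rose by 0.91, and Glul, glutamine synthetase, and Rhbg had changes of -0.66 and -0.84 (adjusted p = 0.00377 and 0.00425). Altogether 892 genes passed, 455 higher and 437 lower, of which 130 rose and 12 fell by 2-fold or more; 551 passed without control replicate 1. Without a pair of arrays at 15 and 75 that were doubted after the data were seen, 917 passed, 886 of them among the 892.

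On day 7 in females at 150 mg/kg-day, several P450 and conjugation genes were far above dose 0, as was the exporter gene Abcc4. Cyp2c55 rose 94.5-fold, from 6.36 ± 0.64 to 12.92 ± 0.17 (SD, n = 4 each; adjusted p = 1.3e-20), and Cyp2b10 rose 45.8-fold, from 8.09 ± 0.53 to 13.61 ± 0.05. Sult1e1, the estrogen sulfotransferase, rose from 4.96 ± 0.98 to 9.09 ± 1.20, a log2 change of 4.14 ± 0.54 (SE; adjusted p = 4.89e-08). Pnliprp1, a pancreatic lipase relative, rose 9.14-fold, the retinoic acid hydroxylase Cyp26a1 8.24-fold, Abcc4 7.34-fold, Cyp2c65 at least 6.99-fold and Cyp2d12 5.73-fold. Serpina4-ps1, a serpin pseudogene, fell by 3.19 ± 0.61 (SE), while Hectd2os, Rdh9, Tmed6 and Hsd17b6 were 4.80-fold, 3.03-fold, 2.36-fold and 2.26-fold lower.

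CAR targets and oxidation enzymes had 12 rises and 0 falls of 28 in females on day 7, with 16 and 1 adjusted over the list alone. Among conjugation enzymes 13 of 32 rose and 0 fell, 16 and 1 adjusted over the list alone, and Gstm3 and Sult1c2 rose 5.14-fold and 2.99-fold. NRF2 targets had 3 rises of 18, 4 adjusted over the list alone, and Ugdh, which makes UDP-glucuronic acid, rose 2.15-fold. PPARα targets and fatty acid oxidation genes moved the other way, with 10 of 27 falling; 14 fell and 1 rose adjusted over the list alone. Plin2, a lipid droplet coat protein, was 1.47-fold lower, a call that ended without control replicate 1, and 5 members fell without control replicate 1 or 2. These 4 shifts stood at adjusted p = 2.63e-06, 0.000319, 0.0125 and 0.00824 with an estimated correlation. Of 49 cell division genes, limma called 0, also adjusted over the list alone; the median change was 0.10, and Mki67 stood at 0.45 (adjusted p = 0.773). Without replicate 3 at 150, 1 cell division gene rose.

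At the preset correlation alone, 9 lists were shifted in females on day 7. Interferon response genes had 5 of 17 rising and 14 adjusted over the list alone (adjusted p = 0.0548 with an estimated correlation), with Cxcl10, an interferon-induced chemokine, up 3.04-fold. Their count of 5 became 2 without control replicate 1, 2 or 4 or replicate 4 at 150, 3 without replicate 1 at 150 and 1 without replicate 2 at 150. Beside them, Kupffer cell markers had a median of 0.34 with 0 of 17 called by limma (adjusted p = 0.374 with an estimated correlation). Acute phase genes had 3 of 22 rising by either adjustment (adjusted p = 0.522 with an estimated correlation), with Orm3 up 4.08-fold. Female-biased genes had 2 of 22 rising, 5 adjusted over the list alone (adjusted p = 0.383 with an estimated correlation); Sult1e1 is a member. Cholesterol synthesis, 0 of 20, and immediate early genes, 0 of 18, were shifted upward with 0 members called by either adjustment in limma (adjusted p = 0.598 and 0.374 with an estimated correlation). Pericentral genes were shifted downward with 1 of 16 rising and 1 falling, 2 and 8 adjusted over the list alone (adjusted p = 0.233 with an estimated correlation); the Wnt target Nkd1 was 1.99-fold lower. Periportal genes had 1 of 12 falling by either adjustment (adjusted p = 0.231 with an estimated correlation), namely Etnppl, which was not called without replicate 3 at 150. Secreted hepatocyte proteins had 1 of 15 falling and 3 adjusted over the list alone (adjusted p = 0.0548 with an estimated correlation); that member, Apoa1, stayed called without control replicate 3, and 0 members fell without any other array. In total 445 genes passed, 277 higher and 168 lower, with 66 rising and 12 falling by 2-fold or more; 244 passed without control replicate 1 and 291 without control replicate 2.

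In males on day 7 at 150 mg/kg-day, 14 of 28 CAR targets and oxidation enzymes and 14 of 17 interferon response genes rose. Cyp2c65 rose from 3.34 ± 0.16 to 10.06 ± 0.40 (SD, n = 4 each), at least 105-fold (adjusted p = 4.01e-21). Cyp2b10 rose 66.7-fold and Cyp2c55 57.8-fold. Nebl, which encodes a nebulin-related actin-binding protein, had the smallest adjusted p of the genes named, 1.71e-26, with a change of at least 3.05 ± 0.16 (SE). Ifit1, an antiviral interferon-induced gene, rose from 6.22 ± 0.53 to 8.47 ± 1.64, or 4.75-fold. Cnmd rose 13.1-fold, the sulfotransferase Sult3a1 at least 11.7-fold, Pnliprp1 11.6-fold, Prom1 10.4-fold, Gm10419 at least 9.18-fold and Moxd1 at least 7.11-fold. Hectd2os was 3.93-fold lower, the transcription factor gene Zbtb16 3.59-fold, Rdh9 2.98-fold, Rdh16f2 2.83-fold and Angptl4, a PPARα target, 2.81-fold.

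CAR targets and oxidation enzymes had 14 of 28 rising and 0 falling in males on day 7, with 20 and 0 adjusted over the list alone; without replicate 1 at 150, 8 rose. Of 32 conjugation enzymes, 15 rose and 0 fell, 19 and 0 adjusted over the list alone, with Gstt3, Gstm3 and Sult1c2 up 5.08-fold, 4.41-fold and 4.14-fold. NRF2 targets had 5 rises of 18, 8 adjusted over the list alone; 2 rose without control replicate 2 or without replicate 2 at 150, and 3 without replicate 1 at 150. Interferon response genes had 14 of 17 rising and 16 adjusted over the list alone, with a median change of 1.46; Usp18, Rsad2 and Cxcl10 rose 4.45-fold, 3.91-fold and 3.75-fold. With an estimated correlation the 4 shifts stood at adjusted p = 1.18e-06, 0.000217, 0.0364 and 0.00198. Beside the interferon genes, Kupffer cell markers shifted upward, with 3 of 17 rising and 13 adjusted over the list alone (adjusted p = 0.142 with an estimated correlation). Mpeg1 rose 2.42-fold, but not past the threshold without replicate 2 at 150, and the marker count of 3 became 6 without control replicate 1, 1 without control replicate 4 and 0 without replicate 2 at 150. Neutrophil markers shifted upward as well, with 2 of 11 rising by either adjustment (adjusted p = 0.383 with an estimated correlation); S100a8 changed by 3.22 ± 0.72 (SE) with a treated SD of 2.66, and by 2.09, not called, without replicate 1 at 150.

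A further 9 lists were called at the preset correlation alone in males on day 7. Cell division genes shifted upward by a median of 0.29 with 1 of 49 rising by either adjustment (adjusted p = 0.629 with an estimated correlation), the riser being Gmnn, which encodes the replication licensing inhibitor geminin, at 2.03-fold. Female-biased genes had 4 of 22 rising, 5 adjusted over the list alone (adjusted p = 0.142 with an estimated correlation). PPARα targets had 1 of 27 rising and 3 falling, 1 and 8 adjusted over the list alone (adjusted p = 0.142 with an estimated correlation); Acadvl was 1.23-fold lower, and the counts were 0 and 1 without replicate 2 at 150, with 0 rising without replicate 1 at 150. Stellate cell markers had 3 of 20 falling and 6 adjusted over the list alone (adjusted p = 0.142 with an estimated correlation), namely Lrat, Reln and Dcn. Cholesterol synthesis had 1 of 20 falling by either adjustment (adjusted p = 0.547 with an estimated correlation); Ebp, the member that fell, was not called without replicate 2 at 150. Gluconeogenesis and periportal genes, each with 0 of 12 called by limma under either adjustment, gave adjusted p = 0.0937 and 0.142 with an estimated correlation. Pericentral genes had 2 of 16 rising and 2 falling, 2 and 5 adjusted over the list alone (adjusted p = 0.511 with an estimated correlation); Lect2 rose 1.56-fold. Secreted hepatocyte proteins had 0 of 15 called by limma and 1 falling adjusted over the list alone (adjusted p = 0.129 with an estimated correlation). Altogether 553 genes passed, 401 higher and 152 lower, with 91 rising and 12 falling by 2-fold or more; 310 passed without replicate 1 and 316 without replicate 2 at 150.

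**Figure D1:**
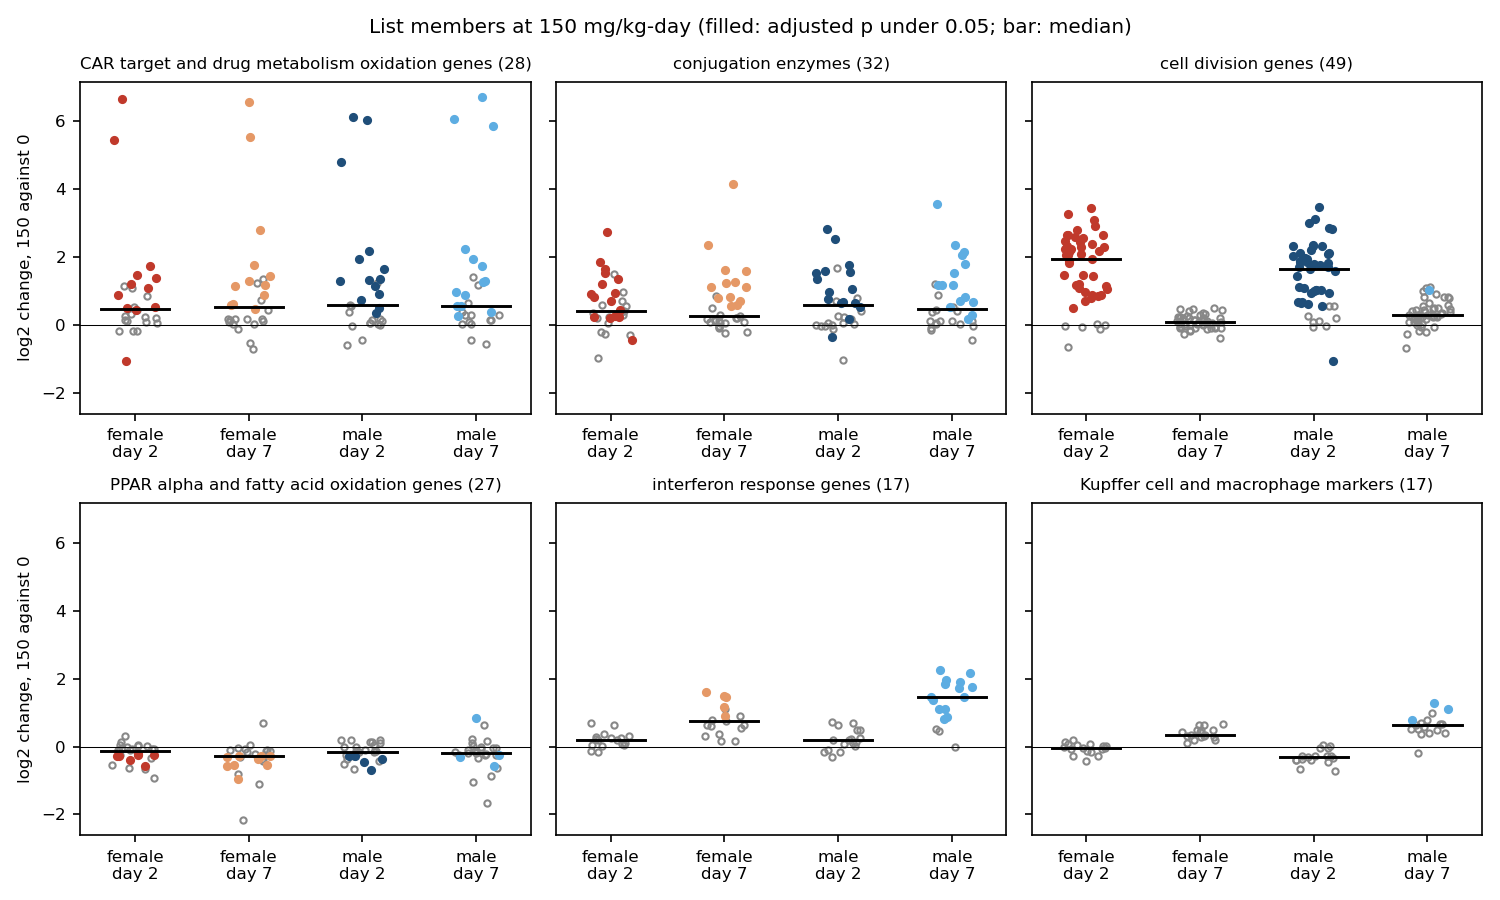
Log2 change at 150 against 0 mg/kg-day (vertical axis) for each measured member of 6 gene lists, by sex and day (horizontal axis); filled points passed adjusted p under 0.05 and bars mark medians. Cell division genes had medians of 1.94 and 1.65 on day 2 in females and males, and 0.10 and 0.29 on day 7.

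The other 14 lists were not called at 150 in either sex on either day. Transporters had 4, 2, 4 and 2 of 17 rising, and 0, 1, 1 and 0 falling, in females on days 2 and 7 and males on days 2 and 7; Abcc3 rose 3.07-fold, 2.63-fold and 2.43-fold in the last 3 of these groups. In the same order, growth and apoptosis regulators had 3, 2, 3 and 3 of 21 rising, with Gadd45b among them in each, up 1.86-fold in females on day 7 (adjusted p = 0.037) and 2.45-fold in males on day 7 (adjusted p = 0.000451). The female day 7 call of Gadd45b ended without control replicate 1, 3 or 4 or without replicate 3 or 4 at 150. AhR targets had 2, 1, 2 and 1 of 7 rising, and bile acid synthesis had 0, 0, 1 and 1 of 12 rising and 4, 1, 0 and 0 falling. Heme synthesis genes, 7 measured, had 1 rise in females on day 2 and 1 fall in males on day 2. Housekeeping genes had 3, 1, 0 and 1 of 9 rising and 1, 0, 1 and 0 falling. ER stress genes had 1 fall of 20 on day 2 in each sex, and circadian genes 1 fall of 17 in females on each day. Pancreas markers had 1 fall of 12 in females on each day, in Cela1, with changes of -0.81 and -0.80. Red blood cell markers had 1 rise of 10 in females on day 7. The 4 measured genes of the imprinted Dlk1-Dio3 cluster, the 19 lymphocyte and NK cell markers, the 13 bile duct markers and the 12 adipose and muscle markers had 0 calls by limma.

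Adjusted over the list alone, transporters had 4, 2, 4 and 3 rises and 2, 1, 3 and 0 falls in that order of groups, growth and apoptosis regulators 3, 2, 3 and 3 rises and 1, 1, 0 and 0 falls, AhR targets 2, 1, 2 and 1 rises and 0, 0, 0 and 1 falls, and bile acid synthesis 1, 0, 1 and 1 rises and 4, 1, 0 and 1 falls. Heme synthesis had 1, 0, 0 and 1 rises and 1, 1, 1 and 1 falls, housekeeping genes 4, 2, 1 and 1 rises and 1, 1, 1 and 0 falls, and circadian genes 0, 1, 0 and 1 rises and 2, 1, 0 and 1 falls. Adipose and muscle markers had 1 rise in females on day 7, and the counts of the other 6 of these lists were the same by either adjustment. The sign of a list's median, mean or camera direction differed only in lists that camera did not call in that group, such as transporters in females on day 2, with a median of -0.02 and a mean of 0.23, and immediate early genes in males on day 7, with 0.05 and -0.13. With the preset correlation, other splits of the same 8 arrays gave up to 13, 13, 18 and 17 shifted lists, against 7, 13, 12 and 15 for the real groups, so chance cannot be excluded for these numbers of lists. Splits with unequal numbers of treated arrays still hold part of the dose effect, so their counts are not those of chance alone.

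Cyp3a11, a target shared by CAR and the receptor PXR, had means between 14.27 and 14.49 at doses 0 and 150 and passed the threshold in no sex or day (adjusted p = 0.0727, 0.266, 0.152 and 0.391); these values lie close to the highest on the arrays, 14.86 to 14.97. Nr1i3, which encodes CAR, fell by 0.86 in males on day 7 (adjusted p = 0.00474), a call that ended without replicate 1 or 2 at 150. Its values elsewhere were -0.36, -0.67 and -0.58 in females on days 2 and 7 and males on day 2 (adjusted p = 0.39, 0.0541 and 0.0812). Ccnd1, the cyclin of G1 phase, had changes of 0.36, 0.24, 0.46 and 0.59 and passed in no group (adjusted p from 0.379 to 0.822); Myc, Meg3 and Nr1i2, the gene of PXR, passed in none either. Members of the Cyp2b, Cyp2c, Gstm, Sult and Ugt2b families resemble each other in sequence, so the gene assigned to a probe set in them is uncertain.

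Of genes higher at 150 on day 2, 340 were shared between females and males, against 15.1 if the calls were independent, and 167 lower genes were shared against 9.4. On day 7 the sexes shared 143 higher genes against 6.1, and 42 lower genes against 1.4. Between days, females shared 123 higher genes against 9.2 and males 145 against 10. In all 4 combinations of sex and day, 88 genes were higher and 21 lower, with Cyp2b10, Cyp2c55, Gstm3 and Abcc3 among the higher and Rdh9 among the lower.

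Lower doses were set against dose 0 in the same way, as shown in the plot of genes changed by dose. At 75 mg/kg-day, Cyp2b10 and Cyp2c55 were again far above dose 0. In females on day 2 Cyp2c55 rose 55.9-fold and Cyp2b10 38.5-fold (SE of the log2 changes 0.43 and 0.40), with Abcc3 up 2.94-fold and Gstm3 3.49-fold. In females on day 7 Cyp2c55 rose 63.3-fold, Cyp2b10 33.5-fold, Gstm3 4.26-fold and Pnliprp1 3.69-fold. For males on day 2 the rise of Cyp2b10 was 5.24 and that of Cyp2c55 4.66, or 5.81 and 5.36 without the pair of doubted arrays, with the P450 genes Cyp2c54 and Cyp2c50 up 2.73-fold and 1.98-fold. Cyp2c65 rose at least 56.7-fold in males on day 7, Cyp2b10 48.7-fold, Cyp2c55 37.6-fold and Cyp2c54 3.25-fold. The CAR list was shifted upward at 75 in each sex and day, with 8, 9, 8 and 7 of 28 members rising in the order used above (adjusted p = 5.32e-05, 4.4e-05, 5.77e-06 and 1.96e-06 with an estimated correlation). Adjusted over the list alone, 11, 13, 12 and 10 rose. Conjugation enzymes had 7, 8, 7 and 8 rises, and 14, 13, 10 and 13 adjusted over the list alone (adjusted p = 0.00984, 0.00803, 0.046 and 0.00093 with an estimated correlation).

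Other lists passed at 75 mg/kg-day in females. PPARα targets were shifted downward, with 3 members falling on each day, 6 and 12 adjusted over the list alone (adjusted p = 0.0287 and 0.0157 with an estimated correlation), and NRF2 targets upward, with 2 rising on each day by either adjustment (adjusted p = 0.00984 and 0.0157 with an estimated correlation). Interferon response genes had 3 rises on day 7, 15 adjusted over the list alone, and a median of 0.83 (adjusted p = 0.0157 with an estimated correlation), beside Kupffer cell markers with a median of 0.68 and 1 rise, 15 adjusted over the list alone (adjusted p = 0.0648 with an estimated correlation). At 75 in males on day 2, 4 cell division genes rose, 36 adjusted over the list alone (adjusted p = 0.0672 with an estimated correlation). Genes passing at 75 numbered 82 in females on day 2, 56 higher and 26 lower; 49 passed without control replicate 2 and 43 without replicate 4 at 75. In females on day 7, 139 passed, 80 higher and 59 lower; 57 passed without control replicate 1, 73 without control replicate 2, 281 without replicate 2, 29 without replicate 3 and 245 without replicate 4 at 75, and 45 passed in a fit on only the arrays of these females. For males on day 2 the count was 80, 66 higher and 14 lower; 48 genes passed without control replicate 1, and 125, 43, 20 and 44 without replicates 1, 2, 3 and 4 at 75. Without the doubted pair of arrays 130 passed, 78 of them among the 80. In males on day 7, 45 genes were higher and 0 lower, with 1571 genes at an unadjusted p under 0.05.

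**Figure D2:**
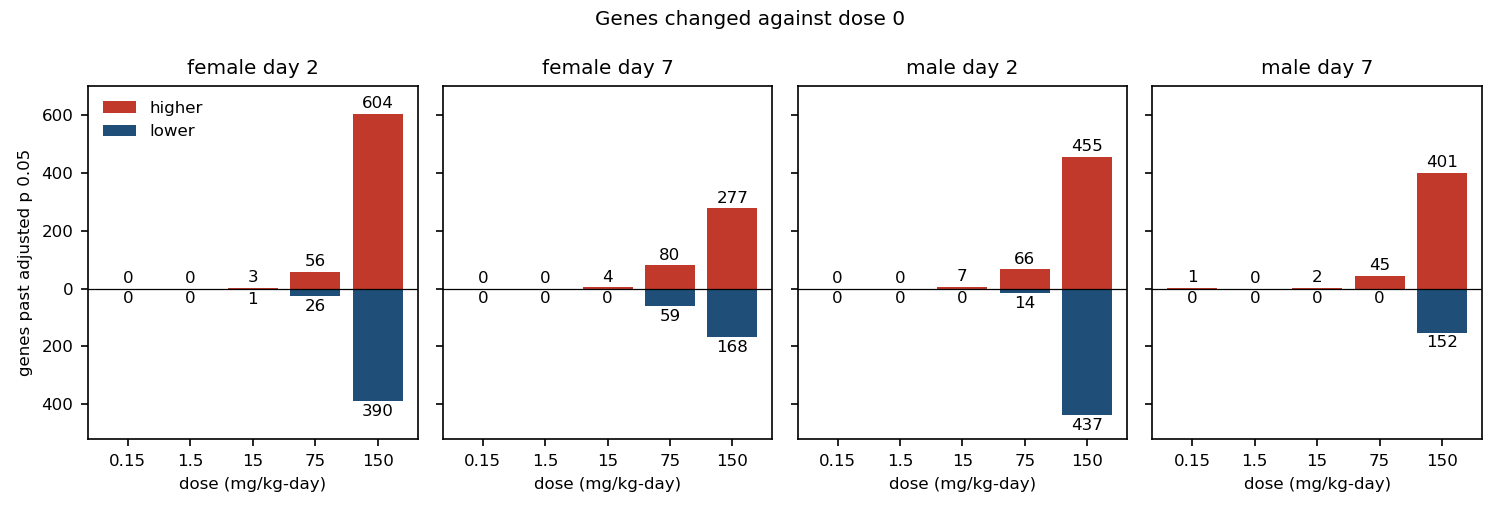
Numbers of genes past adjusted p under 0.05 against dose 0 (vertical axis, higher above and lower below 0) at 5 doses (horizontal axis, mg/kg-day, not to scale), by sex and day. Counts ran from 2 to 7 at 15 mg/kg-day and from 445 to 994 at 150 mg/kg-day.

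At 15 mg/kg-day few genes passed, and Cyp2b10 and Cyp2c55 did so in each sex and day. Cyp2b10 rose 9.40-fold in females on day 2 (adjusted p = 1.79e-07), 8.78-fold in females on day 7 (adjusted p = 5.17e-07), 20.6-fold in males on day 2 and 13.0-fold in males on day 7. Cyp2c55 rose 5.03-fold, 4.63-fold, 8.08-fold and 5.66-fold in the same order. Cyp2c29, another P450, rose by 0.40 and 0.38 in females on days 2 and 7, at a level near the top of the scale. Ribc2 fell by 0.57 in females on day 2, and Anxa7 rose by 0.37 in females on day 7. In males on day 2, Cyp2c54, Cyp2c50, Cyp2c37, Sult1d1 and the transporter gene Slc22a26 also rose, the last by 2.37 ± 0.45 (SE); Cyp2c37 and Sult1d1 were chosen after their values were seen. The CAR list was shifted upward there, with 5 members rising and 8 adjusted over the list alone (adjusted p = 0.000115 with an estimated correlation). List tests at 15 and 75 in these males were not rerun without the doubted pair of arrays. Replicate 1 at 15 in these males had a Cyp2b10 value of 13.66 against 11.07 to 11.29 in the other 3, and replicate 1 at 75 had 10.98 against 13.19 to 13.36; these are the doubted pair. Without them, 5 genes passed in males on day 2: Cyp2b10 at 3.75, Cyp2c55 at 2.10, Cyp2c54 at 1.04, Cyp2c50 at 0.72, and Mfsd4b4, chosen after its values were seen, at -0.48 (adjusted p = 0.0206). The counts at 15 were 4 in females on each day, 7 in males on day 2 and 2 in males on day 7. In females on day 2 the count was 2 without control replicate 2, when Cyp2c29 and Cyp2c55 were not called, and 2 without replicate 2 at 15, when Ribc2 and Cyp2c55 were not. In females on day 7 it was 1 without control replicate 1 or replicate 1 at 15 and 2 without replicate 2 at 15; Cyp2c55 and Cyp2c29 were not called without each of these 3 in turn, and Anxa7 was called in 1 of 8 fits without an array. Slc22a26 in males on day 2 was not called without replicate 1 at 15. The male day 7 count was 5 without control replicate 2. A fit on only the arrays of males on day 2 called 1 gene at 15.

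At 0.15 and 1.5 mg/kg-day Cyp2b10 and Cyp2c55 did not pass. Cyp2b10 differed from dose 0 by 0.71, 0.53, 0.26 and 0.82 at 1.5 (SE 0.40; adjusted p of at least 0.998), and Cyp2c55 by -0.06, 0.48, 0.26 and 0.98. Zfp93, a zinc finger gene, rose by 0.57 ± 0.11 (SE) at 0.15 in males on day 7 (adjusted p = 0.0422), although its treated arrays did not all lie above the controls; it was not called without replicate 1, 2 or 3 at 0.15 or without control replicate 1, 2 or 4, and the count of genes was 0 without these arrays other than control replicates 1 and 2. With all arrays, 1149 genes had an unadjusted p under 0.05 at 0.15 in these males. There, 2 genes passed with dim genes left out, and limma called 0 in a fit on only their arrays or with all probe sets. Otherwise limma called 0 genes: 1436 and 808 genes had an unadjusted p under 0.05 at 0.15 and 1.5 in females on day 2, 781 and 640 in females on day 7, 759 and 820 in males on day 2, and 771 at 1.5 in males on day 7, where 909.7 are expected by chance. A count of 1 appeared at 1.5 without control replicate 2 in females on day 2, without replicate 3 at 1.5 in females on day 7 and without control replicate 4, with only the arrays compared or with the replicate block in males on day 7, and at 0.15 with all probe sets in females on day 2 or without replicate 1 at 0.15 in males on day 2. PPARα targets had a median of -0.20 at 0.15 in females on day 7 and were shifted downward by camera (adjusted p = 0.0287 with an estimated correlation), with 0 members called by limma under either adjustment, where 781 genes had an unadjusted p under 0.05.

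Benchmark doses asked at which dose a fitted curve left the baseline by 1 pooled SD. For Cyp2b10 they were 0.919 mg/kg-day (95% interval 0.547 to 2.95) in females on day 2, 0.926 (0.551 to 2.96) in females on day 7, 2.87 (0.784 to 10.7) in males on day 2 and 0.896 (0.487 to 3.11) in males on day 7. For Cyp2c55 they were 2.66 (1.20 to 5.73), 4.38 (1.80 to 8.45), 3.26 (1.26 to 13.1) and 1.91 (1.17 to 5.41) in the same order. For Gadd45b they were 23.4 (9.32 to 60.3), 41.7 (15.4 to 71.7), 30.5 (8.41 to 74.9) and 28.6 (12.3 to 63.8). In females on day 7 the fitted baseline of Gadd45b was 6.93 and the pooled SD 0.24, but the mean at dose 0 was 7.18. The value of 41.7 is thus about where the curve returned to the level of dose 0, not where it rose above it. Mki67 had benchmark doses on day 2 alone, 61.8 (5.54 to 124) in females and 53.0 (13.0 to 62.5) in males, since it was not called at 150 on day 7. The exponent lay at its limit of 1 for Cyp2b10 except in males on day 2, for Cyp2c55 in males on both days and for Gadd45b in males on day 2. The midpoint lay at its limit of 300 for Gadd45b in males on both days and Mki67 in females. These values depend on the limits set. The pooled SD of Cyp2b10 in females on day 2, 0.39, was below its SD at dose 0, 0.8. The same held in females on day 7, with 0.41 against 0.53, and in males on day 7, with 0.57 against 0.92. In males on day 2 the pooled SD was the larger, at 0.85 against 0.39. Without the doubted pair, the values for males on day 2 were 2.34, 2.89, 22.9 and 52.4 for Cyp2b10, Cyp2c55, Gadd45b and Mki67. In females on day 2, leaving out a replicate of 1 number at every dose gave 0.515, 1.83 and 1.56 for Cyp2b10 without replicates 1, 2 and 3, 1.72 for Cyp2c55 without replicate 4, 48.8, 9.45 and 42.7 for Gadd45b without replicates 1, 2 and 4, and 11.4 and 92.9 for Mki67 without replicates 1 and 3. In males on day 2 it gave 1.62 and 5.52 for Cyp2b10 and 19.8 and 54.9 for Gadd45b without replicates 1 and 2, and 33.3 for Mki67 without replicate 4. With 2 pooled SD as the response level, Cyp2b10 stood at 1.98, 1.99, 4.75 and 1.98 in females on days 2 and 7 and males on days 2 and 7, Cyp2c55 at 4.86, 7.29, 7.97 and 4.10, Gadd45b at 44.3, 67.3, 68.0 and 52.1, and Mki67 at 121 in females on day 2. An exponential curve gave 2.52 and 26.3 for Cyp2c55 and Gadd45b in females on day 7, 1.63 and 21.3 for Cyp2b10 and Mki67 in males on day 2 and 1.39 for Cyp2b10 in males on day 7.

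**Figure D3:**
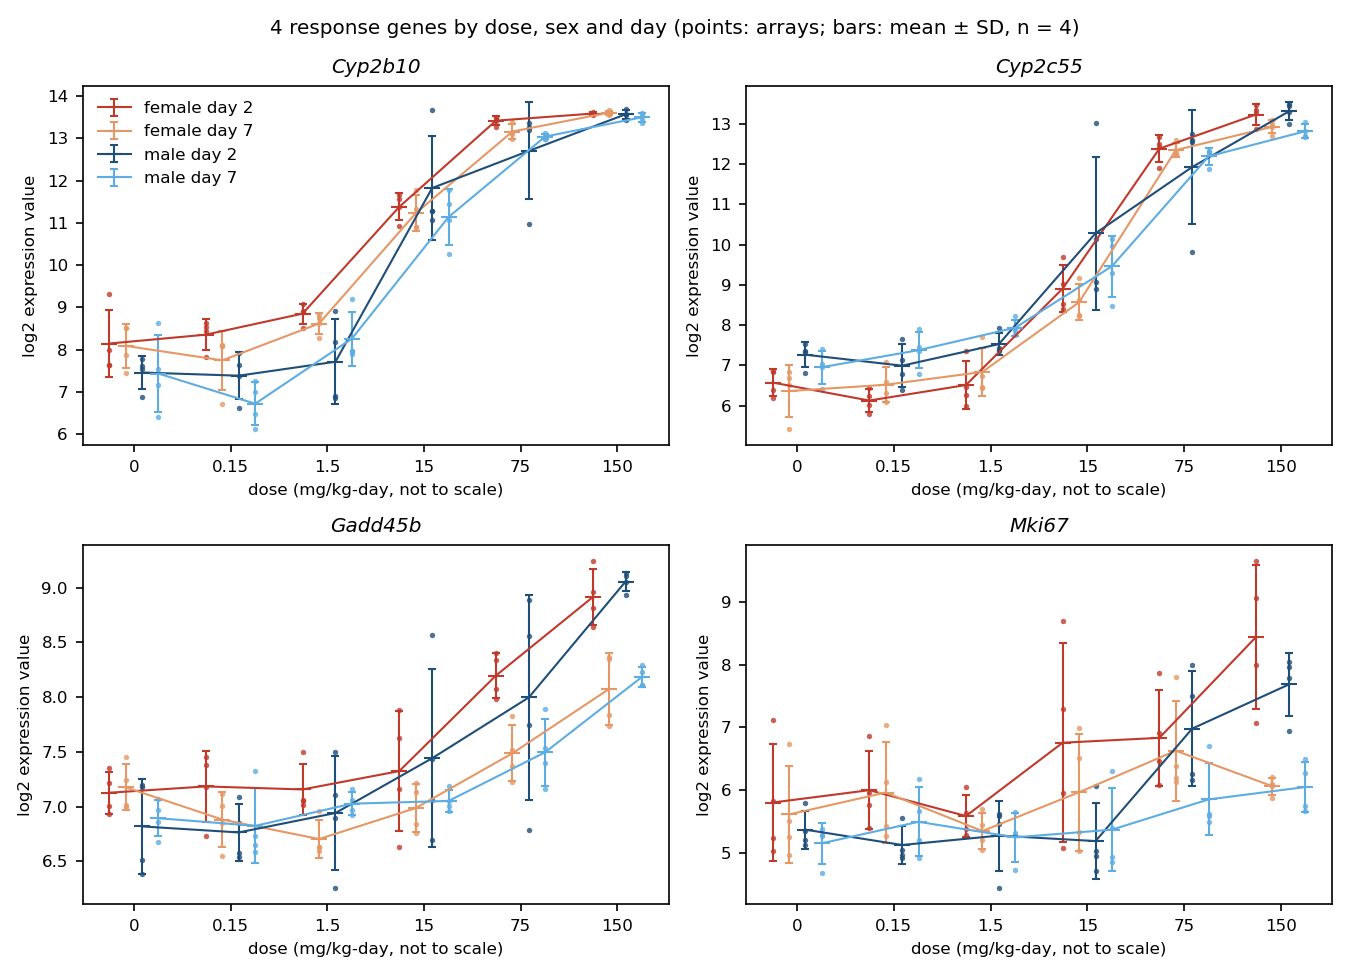
Expression (log2, vertical axis) of Cyp2b10, Cyp2c55, Gadd45b and Mki67 by dose (mg/kg-day, not to scale), sex and day; points are arrays and bars are the mean and SD of 4. Cyp2b10 at 150 mg/kg-day had means between 13.49 and 13.61 in the 4 combinations of sex and day.

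The response at 150 was compared between days within each sex. In females the cell division genes that were high on day 2 were not so on day 7: 32 of 49 had a lower response on day 7, with a median difference of -1.83 (adjusted p = 0.00137 with an estimated correlation). Bub1, a spindle checkpoint kinase, changed by 2.59 on day 2 and -0.09 on day 7, a difference of -2.68 ± 0.52 (SE; adjusted p = 0.000965). Rrm2 had responses of 2.66 and -0.16. In males the median difference of cell division genes was -1.17, with 2 genes called lower (adjusted p = 0.0567 with an estimated correlation). Pnliprp1 had a higher response on day 7 than on day 2 in both sexes, by 2.19 in females and 2.72 in males, as had Nebl, by 1.53 and 2.40. Cyp2d12 and Chil1 did so in females, by 2.08 and 1.47, and Moxd1 in males, by 2.84. The dose 0 means of Bub1, Nebl and Moxd1 lie within or below the lower quartiles of the arrays, so their responses are bounds and the sizes of their differences are uncertain. Interferon response genes differed by a median of 1.21 between the days in males (adjusted p = 0.0653 with an estimated correlation), beside Kupffer cell markers with a median of 0.93 (adjusted p = 0.181 with an estimated correlation). In females 159 genes differed between days, 14 higher and 145 lower on day 7; 93 did without day 7 control replicate 4, and 65, 82 and 268 without replicates 1, 2 and 4 of day 2 at 150. In males 24 differed, 15 higher and 9 lower. Leaving out a day 2 control gave 14, 39 and 8 for replicates 1, 2 and 3, leaving out day 7 control replicate 3 gave 12, leaving out replicate 1 or 4 of day 2 at 150 gave 12 and 13, and leaving out replicate 2 or 3 of day 7 at 150 gave 9 and 47. Fits on only the arrays of each sex called 56 genes in females and 99 in males, and with dim genes left out, which removed 68 and 11 of the called genes from the test, 87 and 11 differed.

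The response at 150 was also compared between the sexes. Cyp2c65 rose more in males than in females on both days, by 3.65 ± 0.62 (SE; adjusted p = 0.00166) on day 2 and by 3.92 ± 0.62 (SE; adjusted p = 3.94e-05) on day 7. On day 7 the response of Gm10419 was 3.20 in males and 0.42 in females, that of Moxd1 2.83 and 0.12, and that of the potassium channel gene Kcnk1 2.43 and 0.04. For Cyp2c65, Gm10419 and Moxd1, with dose 0 means in that same dim range, the sizes of these differences are uncertain. Chil1 went the other way, with 0.07 in males and 1.50 in females, as did Rhobtb1, with -0.60 and 0.49. Elovl3, a fatty acid elongase, had responses of -0.66 and 2.31 in males and females (adjusted p = 0.013), which did not pass without female control replicate 3, male control replicate 2 or male replicate 1 at 150. For cell division genes the median difference on day 2 was -0.28 (adjusted p = 0.814 with an estimated correlation), and for interferon response genes on day 7 it was 0.53 (adjusted p = 0.632 with an estimated correlation), beside 0.31 for Kupffer cell markers (adjusted p = 0.862 with an estimated correlation). In all, 1 gene differed between the sexes on day 2, Cyp2c65, and 16 on day 7, 12 with a higher response in males and 4 in females. Leaving out dim genes removed 11 of these 16 from the test, and 4 differed on day 7. It also removed Cyp2c65, so 0 genes were called by limma on day 2; in a fit on only the arrays compared, which holds Cyp2c65, limma called 0 as well, and with all probe sets 2 genes differed. On day 2 the count was 2 without replicate 2 of either sex at 150 and 3 without male replicate 3 at 150; with all arrays 652 genes had an unadjusted p under 0.05.

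Among untreated mice the sexes differed widely, which gives the background for these comparisons. Cyp4a12a, an arachidonic acid hydroxylase, averaged 12.54 in males and 5.41 in females, and Elovl3 12.28 and 7.77. The sulfotransferases Sult2a2 and Sult3a1 averaged 12.76 and 10.86 in females and 4.06 and 3.21 in males. Cyp2b9 was higher in females, at 11.51 against 5.94, and so was Cyp2b13, at 11.16 against 5.68. The Y-linked genes Eif2s3y and Kdm5d, at 3.23 and 3.05 in females, differed by at least 5.60 and 4.00. With 8 arrays of each sex, 1864 genes differed, 677 higher in males and 1187 higher in females. With the replicate number as a block, 1136 did. As coded, that block places each group at its fitted replicate 1 level. This cancels within a sex and day but not between the sexes, so 1136 and 1864 are not counts of the same comparison.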

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

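The tests of exchanged arrays, of an array of dose 150, of variation between mice, of array brightness, of the share of hepatocytes and of Kupffer cells were chosen only after the result was seen; the count of interferon genes with 1 array left out was planned before.

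In males on day 2, replicate 1 at 15 mg/kg-day had a Cyp2b10 level far above its group, and replicate 1 at 75 had one near the 15 group. Dixon's ratio for Cyp2b10 was 0.916 in the former (13.66 against 11.07 to 11.29) and 0.925 in the latter (10.98 against 13.19 to 13.36), and for Cyp2c55 it was 0.934 in the latter (9.82 against 12.54 to 12.74). Array brightness stays open: 0 of the 2 arrays lay outside the range of the other 94 in median or upper quartile, but the authors' normalization had aligned these. Exchanged dose labels may account for the pattern: over 174 genes picked in the other 3 combinations of sex and day, 2 of 2 arrays lay nearer the opposite dose, at positions of 1.03 and 0.69 on a line from their own dose at 0 to the opposite dose at 1. The array at 15 was above the other arrays at 75 in Cyp2b10, however, and within those at 150 (13.44 to 13.70), as it was in Cyp2c55 (13.01, against 12.54 to 12.74 at 75 and 12.99 to 13.49 at 150). A further score used 97 genes that differ between 75 and 150 in the other 3 combinations of sex and day. On a line from 75 at 0 to 150 at 1, the array at 15 lay at -0.19. That is just below the other arrays at 75 (-0.13 to 0.15), on the side away from those at 150 (0.72 to 1.17). These genes place it near 75 and far from 150, whereas Cyp2b10 and Cyp2c55 place it among the arrays at 150. The values conflict, so an array of dose 150 is neither shown nor excluded. Mice that differed in response or intake, the biological explanation, cannot be told apart from an exchange: a Fisher test of 2 of 8 arrays nearer the opposite dose against 0 of 24 elsewhere (exact two-sided p = 0.0565) rests on the arrays that prompted it and decides nothing, and no other value here excludes such mice.

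In males on day 7 at 150 mg/kg-day, 14 of 17 interferon response genes rose, and their mean score was 1.33 above dose 0 (0.97 ± 0.77 against -0.36 ± 0.24, SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest 4 against 4 arrays allow). A lower share of hepatocytes that raises the other cell types alike is argued against. The score rose by 1.35 over the mean of endothelial, stellate, lymphocyte and bile duct markers (exact permutation p = 0.0286, again the smallest possible). That p adds little to the p of the interferon score itself, since the mean of those markers differed by -0.01 (exact permutation p = 0.8). The argument rests on the markers, which differed by 0.02, -0.24, 0.21 and -0.05 in that order, each far below 1.33. A share lowered by incoming immune cells alone need not raise the endothelial, stellate and bile duct markers, so it is not covered. The difference of 0.21 in lymphocyte and NK cell markers had an exact permutation p = 0.0571. Neutrophil markers, outside that mean, differed by 0.63 (exact permutation p = 0.0571). That 1 array carries it is argued against by the lowest count without an array, 12 members, reached without replicate 2 at 150. More Kupffer cells or macrophages remain possibly a part of it: their score was 0.63 higher, and the interferon score rose by 0.71 over theirs, with an exact permutation p = 0.0857 that decides nothing; macrophages also express interferon genes. An interferon response within liver cells that follows the dose is a further hypothesis, which was not tested.

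For the 4 benchmark genes in the 24 groups, 13 of 96 combinations of gene and group had an array far from the other 3 by Dixon's ratio, against 4.8 expected, since chance gives about 1 in 20. Cyp2b10 gave 0.966 in female day 7 replicate 1 at 0.15 (6.71 against 8.08 to 8.12) and 0.933 in male day 7 replicate 4 at 1.5 (9.21 against 7.89 to 7.98). Cyp2c55 gave 0.846 in male day 2 replicate 4 at 1.5 and 0.898 in male day 7 replicate 2 at 75. Gadd45b gave 0.916 in female day 2 replicate 2 at 1.5 and 0.919 in female day 7 replicate 4 at 1.5. Mki67 gave 0.850 in female day 7 replicate 3 at 75, 0.830 in male day 7 control replicate 4, 0.858 in male day 2 replicate 3 at 1.5 and 0.903 in male day 7 replicate 1 at 75.

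Responses at 150 differed between the sexes by a test of the difference, given as male minus female on the log2 scale. Cyp2c65 differed by 3.65 on day 2. It was the only gene called there, was not called in a fit on only the arrays compared, and 5 of 100 splits gave a count as large. On day 7 the differences were 3.92 for Cyp2c65, 2.78 for Gm10419, 2.71 for Moxd1, 2.39 for Kcnk1, 1.97 for Meig1, -2.97 for Elovl3, -1.42 for Chil1, -1.08 for Rhobtb1 and -0.53 for Cpne1. The dose 0 means of Cyp2c65, Gm10419, Moxd1 and Meig1 lie within or below the lower quartiles of the arrays, so their responses are bounds and the sizes of their differences are uncertain. Cpne1 was not called without male replicate 1 at 150, and Elovl3 was not called without female control replicate 3, male control replicate 2 or male replicate 1 at 150.

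Responses at 150 differed between the days in the same way, given as day 7 minus day 2. In females the differences were 2.19 for Pnliprp1, 2.08 for Cyp2d12, 1.53 for Nebl, 1.47 for Chil1, 1.02 for Dclre1a, -2.97 for Birc5, -2.87 for Esco2, -2.82 for Rrm2, -2.69 for Cdkn3 and -2.68 for Bub1, and the median over cell division genes was -1.83. In males they were 2.84 for Moxd1, 2.72 for Pnliprp1, 2.40 for Nebl, 1.79 for Smpx, 1.67 for Gm10419, -2.21 for Rrm2, -1.91 for Zwilch, -1.80 for Fignl1, -1.59 for 4930579G24Rik and -1.31 for Tcf19. The sizes are uncertain in the same way for Nebl, Esco2 and Bub1 in females and for Moxd1, Nebl, Smpx, Gm10419, Zwilch and Fignl1 in males. Leaving out an array ended the call of Birc5 in females in 10 of 16 fits, and of Fignl1, 4930579G24Rik and Tcf19 in males in 9, 7 and 10 fits; it ended the male calls of Rrm2 without day 2 control replicate 1 and of Zwilch without day 2 replicate 1 at 150.

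Probe sets with several gene symbols or none, 10092 in number, were not used in the comparisons. Past the threshold at 150 were 99 of them in females on day 2 (63 higher, 36 lower), 54 in females on day 7 (31 and 23), 72 in males on day 2 (40 and 32) and 64 in males on day 7 (41 and 23).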

How the results depend on the processing

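The fits without the pair of doubted male day 2 arrays, and the counts of list members under other settings, were chosen only after the result was seen; the other alternatives were planned. No result turned its direction. Quantile normalization changed none of 43 results past 1.5 times or over the threshold, nor did a trend and robust variance in limma for 25. Leaving out dim genes kept 24 of 29 results, all probe sets 22 of 25, only the arrays compared 18 of 25, the replicate block 27 of 29 and the doubted arrays 8 of 9. Of 14 benchmark doses, 9 stayed within 1.5 times with an exponential curve and 1 with 2 pooled SD. A pseudocount was not run, as the values are logarithms. Signal over background is not given in the sources used here, so its limit is unknown. Except where fewer genes, fewer arrays, a higher response level or the coding of the block between the sexes act by construction, the cause was not tested.

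Without dim genes, 2 genes passed at 0.15 in males on day 7, 0 (limma; 652 genes at an unadjusted p under 0.05 with all genes) and 4 differed between the sexes on days 2 and 7, and 87 and 11 between days in females and males. With all probe sets, 1 passed at 0.15 in females on day 2, 0 at 0.15 in males on day 7, and 2 differed between the sexes on day 2. With only the arrays compared, 45 passed at 75 in females on day 7, 1 at 15 in males on day 2, 0 and 1 at 0.15 and 1.5 in males on day 7, 0 differed between the sexes on day 2, and 56 and 99 differed between days in females and males. With the replicate block, 1 passed at 1.5 in males on day 7 and 1136 differed between untreated sexes, the latter at the fitted level of replicate 1. Without the doubted arrays, 130 passed at 75 in males on day 2. With an estimated correlation, 4, 5 and 4 lists were shifted in females on day 7 and males on days 2 and 7. With 2 pooled SD, benchmark doses in females on days 2 and 7 and males on days 2 and 7 were 1.98, 1.99, 4.75 and 1.98 for Cyp2b10, 4.86, 7.29, 7.97 and 4.10 for Cyp2c55 and 44.3, 67.3, 68.0 and 52.1 for Gadd45b, and 121 for Mki67 in females on day 2. With an exponential curve, they were 2.52 and 26.3 for Cyp2c55 and Gadd45b in females on day 7, 1.63 and 21.3 for Cyp2b10 and Mki67 in males on day 2 and 1.39 for Cyp2b10 in males on day 7.

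With 1 array left out, females on day 2 had 0 to 1 genes at 1.5 (limma; 808 at an unadjusted p under 0.05 with all arrays), 2 to 4 at 15, 43 to 88 at 75 and 601 to 1049 at 150. Females on day 7 had 0 to 1 at 1.5, 1 to 3 at 15, 29 to 281 at 75 and 244 to 402 at 150. Males on day 2 had 0 to 1 at 0.15, 20 to 125 at 75 and 551 to 833 at 150. Males on day 7 had 0 to 1 at 0.15 and 1.5, 2 to 5 at 15 and 310 to 617 at 150. Between the sexes on day 2, 1 to 3 genes differed, and between days 65 to 268 in females and 8 to 47 in males. Without the arrays of 1 replicate number at every dose, benchmark doses in females on day 2 ran from 0.515 to 1.83 for Cyp2b10, 1.72 to 3.57 for Cyp2c55, 9.45 to 48.8 for Gadd45b and 11.4 to 92.9 for Mki67; in males on day 2 they ran from 1.62 to 5.52 for Cyp2b10, 19.8 to 54.9 for Gadd45b and 33.3 to 52.2 for Mki67, and those of the other genes and groups stayed within 1.5 times. Of 3936 values of named genes with 1 array left out, 3473 kept their side of the threshold, 442 lost the call and 21 gained one.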

Other observations

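The 4 tests of splits for differences between sexes or days at 150 were chosen only after the result was seen, in place of a planned form that left the dose effect in; the other split tests were planned.

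Among genes listed as higher in female liver, several rose in males at 150 mg/kg-day. Sult3a1 in males on day 7 rose from 3.20 ± 0.31 to 6.74 ± 1.51 (SD, n = 4 each; adjusted p = 0.00317), against 10.86 in untreated females of both days. Prom1, a stem cell surface marker, rose from 5.75 ± 0.72 to 8.08 ± 0.41 in males on day 2 and from 5.29 ± 0.24 to 8.67 ± 1.50 on day 7, with 8.71 ± 0.65 and 8.90 ± 0.29 in untreated females on days 2 and 7; it rose in females at 150 too, to 10.31 and 10.64. The list of female-biased genes was not shifted in males with an estimated correlation (adjusted p = 0.343 and 0.142 on days 2 and 7).

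Crp, which encodes C-reactive protein, rose in males by 0.41 ± 0.09 on day 2 and 0.37 ± 0.09 on day 7 (SE; adjusted p = 0.00067 and 0.00393), and Orm3 rose 4.49-fold on day 7, while the acute phase list as a whole was not shifted in males (camera adjusted p = 0.168 and 0.329). Akr1d1, a reductase of bile acid synthesis, rose in males on day 2 by 0.68 (adjusted p = 0.000589). The phosphatidylcholine transporter gene Abcb4 fell by 0.60 in females on day 7 (adjusted p = 0.00107). At 15 mg/kg-day in females on day 2, cell division genes had a median of 0.49 with 0 members called by limma (921 genes at an unadjusted p under 0.05; adjusted p = 0.59 with an estimated correlation).

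Splits of the 8 arrays of a comparison into 4 and 4, 35 in number, asked whether chance could give as many genes. At 150 chance can be excluded in each sex and day, with 1 split of 35 as large: 994 genes against at most 402 in another split in females on day 2, 445 against 73 in females on day 7, 892 against 16 in males on day 2 and 553 against 78 in males on day 7. At 75 chance can be excluded likewise, with 82 against 2, 139 against 20, 80 against 19 and 45 against 3. At 15 no other split was as large in females on day 7 (4 against 1), males on day 2 (7 against 1) and males on day 7 (2 against 1). With counts this small, a share of 1 in 35, uncorrected for the number of split tests, does not firmly exclude chance for them. In females on day 2, 2 splits were as large, so chance cannot be excluded. The other split gave 69 genes against 4. So many calls may point to a structure of these samples beside the dose, which was not tested. At 0.15 and 1.5 the splits decide nothing where the real groups gave 0 genes in limma, since all 35 are then as large by construction (the counts at an unadjusted p under 0.05 run from 640 to 1436); other splits gave at most 1 and 0 in females on day 2, 0 and 1 in females on day 7, 1 and 7 in males on day 2 and 2 at 1.5 in males on day 7. At 0.15 in males on day 7 chance cannot be excluded: 6 splits were as large, with 1 gene against at most 5.

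For the number of lists shifted at 150 with the preset correlation, chance cannot be excluded: 17, 3, 9 and 2 of 35 splits were as large in females on days 2 and 7 and males on days 2 and 7, with 7, 13, 12 and 15 lists against at most 13, 13, 18 and 17. Here too, splits with unequal numbers of treated arrays hold part of the dose effect, so these counts do not show what chance alone gives. For differences at 150, 100 splits were drawn after the effects of dose and of sex or day were removed. For the sex difference on day 7, 1 of 100 was as large, with 16 genes against at most 11. For the day difference, 2 of 100 were as large in females, with 159 against 180, and 1 of 100 in males, with 24 against 18. These shares are uncorrected for the number of split tests and come from a form chosen after the result was seen. They do not firmly exclude chance. For the sex difference on day 2 chance cannot be excluded (5 of 100, 1 against 4). With the dose effect left in, splits mix treated with control arrays and the counts are void; they were 19, 12, 6 and 12 of 100 for the sex difference on days 2 and 7 and the day difference in females and males. For the sexes at dose 0, 1 of 100 drawn splits was as large, so chance can be excluded, with 1864 genes against at most 1364; splits with unequal numbers of each sex still hold part of the sex difference.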
